A study of Mus musculus with 12 samples.

How the data were processed

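Single-cell RNA libraries were made from the right submandibular and sublingual salivary glands of 12 week old female mice, per the labels' protocols. The mice carried a tamoxifen-induced Pdgfra Cre and a Rosa26 tdTomato reporter. Ligation means that a metal clip closed the main ducts of these glands and stayed in place for 1, 3 or 7 days; mice without surgery gave the homeostatic group. Each of the 4 groups holds 3 libraries, and the labels state 3 mice for each time point. Epithelial and red blood cells were depleted with EpCAM and Ter119 antibodies on magnetic beads and dead cells were removed, so shares of acinar, ductal and erythroid cells also reflect that step.

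For each of the 12 libraries a pair of matrices of UMI counts per gene and cell barcode was deposited, a Cell Ranger matrix and a matrix whose name mentions CellBender, a program that removes free RNA. Per the submitters' processing notes the tools were Cell Ranger 8.0.0, Seurat 5.0.1 and R 4.3.1 with genome build GRCm39. Per the file headers, 2 libraries were counted with Cell Ranger 7.0.0, 6 with 7.0.1 and 4 with 8.0.0. The deposited counts use 2 gene annotations. The 3 homeostatic libraries, the 3 libraries of day 3 and 7-day replicates 1 and 2 have Ensembl-named features (32286, with a CreERT2 feature added in homeostatic replicate 3 and 3-day replicate 1). The 3 libraries of day 1 and 7-day replicate 3 have 50768 features named by symbol. The CellBender matrix of 7-day replicate 2 carries the symbol-named annotation while its other matrix carries the Ensembl-named one. The annotation release is not given in the sources used here. The genome given for this work is of an earlier build, so no coordinates are printed.

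Genes were matched between annotations by symbol, giving 25167 shared genes: 24760 with the same symbol, 394 through a synonym in a RefSeq gene table of assembly GRCm38.p6, and 13 mitochondrial genes by name. Genes are named below by symbol, since the symbol-named libraries hold no other identifier. The Cell Ranger counts were the main measurement. Barcodes with at least 300 genes and at most 20% mitochondrial counts were kept (132957 of 137423). Doublets were scored within each library by the share of simulated doublets among a cell's neighbours, and the highest-scoring barcodes were removed at 0.8% of cells per 1000 barcodes, which took out 13469 (10.13%; 5.256% to 14.517% per library). The remaining 119488 cells were clustered on 2000 variable genes, 40 principal components and 20 neighbours with the Leiden method at resolution 1 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2). Of 44 clusters, 41 were named from fixed marker lists and 3 stayed unnamed (3889 cells). A name rested on at least 3 detected markers. Macrophage, monocyte and dendritic clusters were put into 1 class after the data were seen, because their markers overlapped, which left 12 classes.

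Cells were not treated as replicates. Counts were summed over the cells of a class in each library and tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjustment within a comparison, threshold 0.05) in R 4.3.3. All 12 libraries entered 1 fit with an additive term for the annotation. This term is estimated from the 7-day libraries alone, since only that group holds both annotations, and it widens the error of every comparison with day 1. The term moves these folds as well, because the difference of 7-day replicate 3 from 7-day replicates 1 and 2 is taken out of the day-1 values. It also fits 7-day replicate 3 exactly. Day 7 against homeostatic or day 3 thus rests on 7-day replicates 1 and 2, and day 7 against day 1 on 7-day replicate 3 alone. In the CellBender counts 7-day replicate 2 is symbol-named too. There the first 2 comparisons rest on replicate 1 alone and the last on replicates 2 and 3. The annotation term then rests on 7-day replicates 2 and 3 against 7-day replicate 1, so the day-1 values are fitted anew too. Calls lost or gained there, at day 7 or in comparisons with day 1, cannot be assigned to the removal of free RNA. Group means and SDs in CPM use all 3 libraries. As an alternative chosen after seeing the data, the shift of each gene between the annotations was measured within 7-day replicate 2 and taken out of the symbol-named libraries, in place of the term. That shift also contains what CellBender removed from that library. For macrophage-like, endothelial-like and mural-like cells, libraries with at least 20 cells of the class entered. The 18 fixed gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), with an estimated correlation and with fry as alternatives. The lists, the 19 marker lists of cell types and the rule for named genes were fixed before the data were examined. Log2 CPM used a prior count of 2. Fold changes are given as log2 values with their standard error.

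Named genes followed a rule: the 4 genes (3 between days and in other classes) with the largest rise and fall among called genes with a mean log2 CPM of at least 4 and no overlap between groups, and up to a pair of called members of each list with the smallest adjusted p. Mitochondrial, ribosomal, predicted, immunoglobulin and other cell type marker genes were left out. Pdgfra and Pdgfrb were always included. For the alternative with the shift taken out, genes with a shift of 0.5 or more (log2) were left out of the largest changes as well.

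Shares of cells per class were tested with an exact permutation test of the F statistic on the logit share (0.5 cells added to each side) over all 15400 assignments of the libraries to groups, with Benjamini-Hochberg adjustment over the 12 classes. Pairs of groups of 3 cannot give a p below 0.1. A count of 0 was read as a limit of 3 counts. Exact intervals are at a confidence level of 0.95; intervals and floors cover counting error only.

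The tests were run on simulated data first. With the annotation term, genes changed by a log2 fold of 2 were recovered at 19.23% for day 1 against homeostatic among 14666 genes, at 88.61% for day 3 among 14680 and at 90.14% for day 7 among 14681. With the measured shift taken out, the value for day 1 was 88.46%. The simulated libraries held exactly that shift and no other difference between annotations. This value therefore shows the error without the term, not whether the measured shift suffices. Alternatives, whose effect the closing section gives, were RLE scaling, DESeq2 1.42.0, no filter on low counts, the CellBender counts, no annotation term, the replicate number as a block, only the 6 libraries compared, genes with a small annotation shift, stricter cells (at least 800 genes and at most 10% mitochondrial counts), doublets kept, classes from each library alone, resolution 2 for the shares and leaving out each library in turn. Chosen after seeing the data were the shift taken out, leaving out 1-day replicate 2 and 3-day replicate 3 together, the 8 libraries with Ensembl-named features alone, the unnamed clusters added, 150 fibroblast-like cells per library, the dendritic cluster left out, list members in the other classes with the CellBender counts and another denominator for the shares. Within groups, log2 CPM of the fibroblast sums correlated across genes with r from 0.925 to 0.979, and every pair of libraries differed by more than sampling noise, with a chi-square of 4.87 to 573.6 per degree of freedom. Deviations of the fibroblast sums from their group means were correlated between libraries of the same replicate number. All 3 pairs were over 0.1 for homeostatic with day 3 (0.127 to 0.206) and for day 3 with day 7 (0.202 to 0.396), and for no other pair of groups, so the fit with the number as a block is given beside these comparisons where it changes a call; the labels name no shared batch. Figures were drawn with matplotlib 3.10.9.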

Results

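The series follows the stroma of the mouse salivary gland after its ducts were closed, with the response of fibroblasts over time as its stated subject. Single-cell transcriptomes were measured in 12 libraries: 3 homeostatic, and 3 each at 1, 3 and 7 days of ligation. The files hold 137423 cell barcodes and 900083825 UMIs. Homeostatic replicates 1 to 3 had 43809086, 54695117 and 70739675 UMIs, those of day 1 had 83985600, 65058297 and 52556531, those of day 3 had 83129049, 105392917 and 106981115, and those of day 7 had 63360326, 94793976 and 75582136. After filtering, 20490 cells were fibroblast-like. Their summed depth ran from 904177 UMIs in homeostatic replicate 1 to 59706686 in 7-day replicate 2.

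The makeup of the recovered cells was compared first. Neutrophil-like cells were absent from the homeostatic libraries (0 of 33858 cells, which allows a share of up to 0.00886%) and made up 5.90% ± 6.33 (SD, n = 3) of cells at day 1, 11.7% ± 16.6 at day 3 and 1.46% ± 1.97 at day 7. Erythroid-like cells went the other way, from 0.756% ± 0.435 to 0.0833% ± 0.134, 0.00227% ± 0.00393 and 0.00549% ± 0.0095. These were the 2 of 12 classes whose share differed between the groups (exact permutation test, adjusted p = 0.0487 for both). The 3-day neutrophil mean rests on replicate 3, where 30.9% of cells were neutrophil-like against 1.58% in the lowest 3-day library. Erythroid cells were a target of the Ter119 depletion. No class was called when any 1 homeostatic library, 1-day replicate 3, 3-day replicate 3 or 7-day replicates 1 or 2 was left out. The erythroid call was also lost without 3-day replicates 1 or 2 or 7-day replicate 3 (exact permutation test, adjusted p = 0.0547, 0.08 and 0.092), where the neutrophil call was kept. Both calls were also lost with classes made from each library alone (exact permutation test, adjusted p = 0.0701 for both) and within the 8 libraries of Ensembl-named features (exact permutation test, adjusted p = 0.0857 for both). With the replicate number as a block the neutrophil and erythroid calls were lost as well (exact permutation test, adjusted p = 0.0729 and 0.0833).

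Fibroblast-like cells made up 6.56% ± 4.94 of homeostatic cells, 12.2% ± 4.64 at day 1, 19.8% ± 11.4 at day 3 and 38.5% ± 9.08 at day 7 (SD, n = 3 each), which missed the threshold (exact permutation test, adjusted p = 0.068). Without 3-day replicate 2, where they were 6.72% against 27.4% and 25.2% in the other 3-day libraries, their share was called (exact permutation test, adjusted p = 0.0394). Over a denominator without acinar, ductal, erythroid, B and T cells, chosen after seeing the data, the means were 11.1%, 14.4%, 29.0% and 48.2% and the groups differed (exact permutation test, adjusted p = 0.00955). Acinar-like cells averaged 13.7%, 1.59%, 0.183% and 0.459% in the same order (exact permutation test, adjusted p = 0.068; 0.0431 without 1-day replicate 2 and 0.0226 without 3-day replicate 1), and ductal-like cells 19.8%, 5.08%, 0.328% and 0.688% (exact permutation test, adjusted p = 0.101); EpCAM depletion acts on both. Blood endothelial-like cells averaged 38.3%, 45.2%, 20.5% and 24.5%, and macrophage-, monocyte- or dendritic-like cells 4.87%, 12.6%, 3.46% and 8.60% (exact permutation test, adjusted p = 0.146 for both). The 3-day endothelial mean rests on replicate 1 (43.5% against 10.0% and 7.88%), without which this share was called (exact permutation test, adjusted p = 0.00545). Schwann-like cells averaged 0.704%, 2.64%, 0.544% and 2.69% (exact permutation test, adjusted p = 0.101). The lowest barcode of homeostatic replicate 2 had 1545 UMIs against 500 in the other libraries, which can set shares of shallow cells. Unnamed clusters whose best marker list was that of fibroblasts held 25.6% of the cells of 3-day replicate 3 and at most 0.441% of those of any other library, and are not in the fibroblast-like share. In 3-day replicate 2, 30.8% of cells were B- or plasma-like, and 1-day replicate 2 kept 14.3% ductal-like and 4.26% acinar-like cells.

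**Figure D1:**
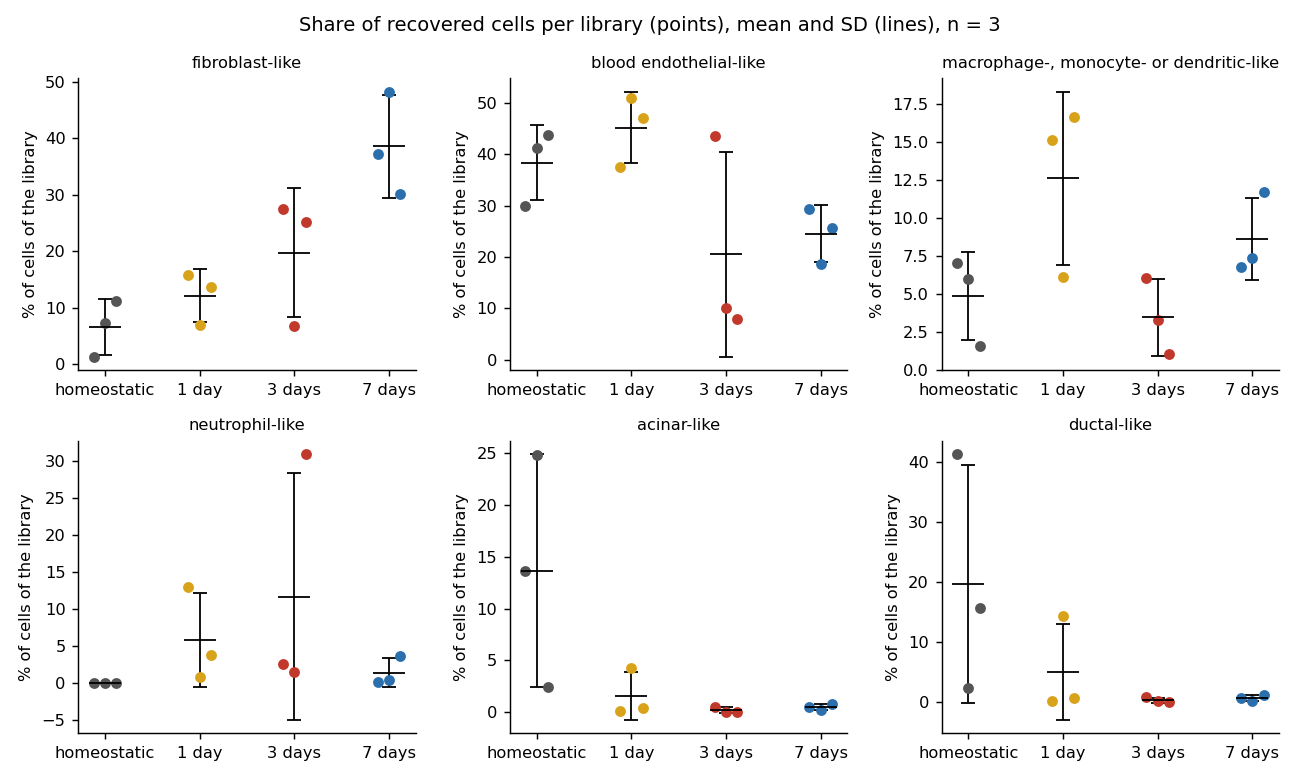
Share of recovered cells (percent of the cells of a library, vertical axis) of 6 cell classes in the 4 groups (horizontal axis); points are libraries, lines the mean and SD of 3 libraries. Fibroblast-like cells average 6.56% in the homeostatic group and 38.5% at day 7, and neutrophil-like cells were found in each of the ligated libraries and in 0 of 33858 homeostatic cells.

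The first question in fibroblast-like cells was how they differed from homeostatic ones at day 1. Serpina3n, an acute-phase serine protease inhibitor, rose by 5.63 ± 0.704 (log2 fold ± SE; adjusted p = 0.0279), from 13.9 ± 7.02 to 411 ± 107 CPM (SD, n = 3). The mitotic kinase Nek6 rose by 2.94 ± 0.424 (adjusted p = 0.0364) and the long non-coding RNA Morrbid by 2.72 ± 0.382 (adjusted p = 0.0355). Through the annotation term, day-1 folds also take in the difference of 7-day replicate 3 from 7-day replicates 1 and 2. In CPM these 7-day values were 95.3 against 151.5 and 193.5 for Serpina3n, and 75.8 against 108.1 and 155 for Morrbid. For Nek6 they were 36.3 against 30.7 and 36.8. Of 14716 genes tested with edgeR's quasi-likelihood test, 13 were called, 4 higher and 9 lower, and 2329 had an unadjusted p below the same threshold. Among the falls, Fgfr2 changed by -2.48 ± 0.363, and its share of counts moves by -2.33 between the annotations within a single library. The other called genes, named after their values were seen, were Cyb561 (higher) and Nrk, Cited1, Rtl3, Atp1b1, Ntn1, Rxrg, Hapln1 and Pthlh (lower). On the CellBender counts edgeR called 0 genes (2589 at an unadjusted p; DESeq2 called 453 on the main counts), and Serpina3n, Nek6, Morrbid and Fgfr2 had adjusted p = 0.0945 to 0.199. In the CellBender counts the annotation term rests on 7-day replicates 2 and 3 against 7-day replicate 1, so these losses cannot be assigned to free RNA. Without the annotation term 3557 genes were called. Leaving out 1 library gave between 0 (homeostatic replicates 1 or 2, 1-day replicate 1, 7-day replicates 1 or 2) and 2051 (1-day replicate 2), with 1 and 4 calls without homeostatic replicate 3 and 1-day replicate 3 and 20 and 21 without 3-day replicates 1 and 3.

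With the measured annotation shift taken out, an alternative chosen after seeing the data, 3224 genes were called at day 1, 1845 higher and 1379 lower, among them all 13. The neutrophil-attracting chemokine Cxcl5 rose by 8.61 ± 1.28 (adjusted p = 0.0049), from 0.896 to 321 CPM, the acute-phase protein Saa3 by 8.57 ± 1.22 and the siderophore-binding Lcn2 by 6.72 ± 0.917 (adjusted p = 0.00453 and 0.00443). Spp1, which encodes osteopontin, rose by 7.06 (adjusted p = 0.0129) and the metalloproteinase inhibitor Timp1 by 6.28 ± 0.873, with matrix metalloproteinase Mmp3 at 4.54 ± 0.709. In 1-day replicate 2 Spp1 stood at 109 CPM and Timp1 at 459, against 3793 and 7516 in replicate 1 and 7601 and 5266 in replicate 3. Cluster 21 held 49.4% of the day-1 cells (18.6% to 67.6% between libraries), and cluster 15 held 74.9% of the homeostatic ones and 48.1% of those of 1 library of day 1. The retinoic acid-making enzyme Aldh1a2 rose by 3.17 ± 0.522. Falls included Dbp, a clock-controlled transcription factor (-4.07 ± 1.12), Apoe (-2.37 ± 0.445), the bone morphogenetic protein Bmp7 (-3.04 ± 0.439) and the transporter Abca6 (-2.99 ± 0.767). Dbp stood at 4.82, 18.6 and 7.60 CPM in 1-day replicates 1 to 3. In symbol-named 7-day replicate 3 it stood at 4.01, against 155.7 and 192.7 in 7-day replicates 1 and 2. Its fall thus cannot be told apart from another difference of the symbol-named libraries. Fxyd2 (-4.23 ± 1.22) and Prol1 (-3.58 ± 1.03), which glandular epithelium expresses, fell in parallel with the ductal markers, of which 7 of 8 were called lower, and the acinar markers, of which 5 of 10 were.

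In the same alternative, 15 of 17 ER protein folding genes rose (15 adjusted over the list alone), among them Sdf2l1 by 2.44 ± 0.285 and Pdia4 by 1.60 ± 0.217. DNA replication genes rose in 11 of 17 cases (Mcm6 by 1.74 ± 0.363) and mitosis genes in 11 of 16 (Top2a by 5.66 ± 1.22), and collagen processing and crosslinking genes in 12 of 18, with 1 lower (Lox by 4.52 ± 0.697, at 101 CPM in 1-day replicate 2 against 812 and 1132). Of 26 chemokine, cytokine and NF-kB target genes 9 rose and 1 fell, of 18 hypoxia and glycolysis genes 9 rose (Ldha by 2.14 ± 0.274), and of 14 matricellular genes 8 rose and 1 fell. These 7 lists passed camera, and none kept its call with an estimated correlation, where the lowest adjusted p was 0.45. With the annotation term 10 lists passed camera although no member was called, the strongest being ER protein folding (adjusted p = 3.9e-09; 12 of 17 members higher adjusted over the list alone; adjusted p = 0.472 with an estimated correlation). Fibrillar collagens were among them with a negative median, which was 0.26 with the shift taken out (adjusted p = 0.63).

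At day 3, Cthrc1, a secreted protein of matrix-producing fibroblasts, rose in fibroblast-like cells over the homeostatic group by 9.72 ± 1.24 (adjusted p = 0.00195), from 0.856 ± 0.33 to 745 ± 217 CPM (SD, n = 3). Tenascin C (Tnc) rose by 8.90 ± 2.01 (adjusted p = 0.0184), the kinesin Kif26b by 8.56 ± 1.41 (adjusted p = 0.00584) and Cxcl5 by 8.55 ± 0.864 (adjusted p = 0.000922). The largest falls were in Scgb1b27 (-6.64 ± 1.86), Scgb2b27 (-6.55 ± 1.72), Fxyd2 (-6.26 ± 1.39) and Prol1 (-4.74 ± 1.13), all genes of gland epithelium; with the replicate number as a block the first 2 lost their call (adjusted p = 0.0898 and 0.0765). Scgb2b27 also lost its call with the CellBender counts (adjusted p = 0.0522), where Scgb1b27 stood at -8.14 and Prol1 at -5.54. Of the acinar markers 8 of 10 were called lower in these cells, of the ductal markers 7 of 8 and of the erythroid markers 5 of 5. In all, 2131 of 14716 genes were called, 1298 higher and 833 lower. With 150 cells per library, 787 were called. Without homeostatic replicates 1, 2 or 3 the count was 1117, 689 and 678, without 3-day replicate 3 it was 1116 and without 1-day replicate 2 it was 3353. Cluster 15 held 74.9% of the homeostatic fibroblast-like cells (49.1% to 94.0% between libraries), and clusters 7 and 4 held 45.7% (24.9% to 84.3%) and 28.4% (0.108% to 53.4%) of those of day 3.

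By list, all 16 mitosis genes rose at day 3, with a median of 5.50; Cenpf rose by 5.34 ± 0.544 and Ube2c stood at 3092 UMIs against 2, a ratio of 246 (exact interval 68.1 to 2033). Matricellular genes rose in 12 of 14 cases, with 1 lower (Thbs2 by 2.38 ± 0.273), and collagen processing and crosslinking genes in 15 of 18 (P4ha2 by 2.62 ± 0.333, Loxl1 by 1.81 ± 0.266). Of 13 fibrillar and fibril-associated collagens 8 rose (Col12a1 by 4.75 ± 0.517, Col16a1 by 1.70 ± 0.205), and of 12 contractile genes 9 rose, led by Lrrc15, a surface protein of activated fibroblasts (8.65 ± 0.58), and the tropomyosin Tpm1 (2.35 ± 0.212). Hypoxia and glycolysis genes rose in 13 of 18 cases (Hif1a by 2.69 ± 0.34, Bnip3 by 1.97 ± 0.267), and in this group 3-day replicate 3 stood higher than the other 3-day libraries by a median of 0.469. Of 16 matrix proteases and inhibitors 7 rose (Timp1 by 5.32 ± 0.84, Mmp23 by 1.81 ± 0.231), of 19 interferon response genes 10 rose and 1 fell (Ifi44 by 2.61 ± 0.327, Irf7 by 2.02 ± 0.26), and of 26 chemokine and cytokine genes 9 rose while Ccl11, the eosinophil attractant, fell (-2.36 ± 0.392). Of 5 neutrophil markers in the same sums 2 were called higher and 1 lower. DNA replication genes rose in 6 of 17 cases (Uhrf1 by 3.99 ± 0.93) and TGF-beta pathway genes in 4 of 15 (Inhba by 2.77 ± 0.46). Basement membrane genes had a median of -0.512 with 0 of 13 called.

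These 12 lists passed camera at day 3; with an estimated correlation none did, the lowest adjusted p being 0.0505. Adjusted over the list alone, the counts of higher members were 16 for mitosis, 13 for matricellular genes, 15 for crosslinking, 8 for collagens, 11 for contractile genes and 14 for hypoxia. Outside these lists, the growth factor neuregulin Nrg1 rose by 6.31 ± 0.962 and Bmp7 fell (-3.41 ± 0.456), and 7 of 24 secreted growth factors rose while 8 fell. Adventitial fibroblast genes rose in 3 of 15 cases with 1 lower (Fbn1 by 1.62 ± 0.287, Mfap5 by 1.75 ± 0.444), complement genes in 3 of 12 (C4b by 2.19 ± 0.521), ER protein folding genes in 2 of 17 with 1 lower (Pdia4 by 0.906 ± 0.211, Herpud1 at -1.10 ± 0.245), immediate-early genes in 2 of 20 (Egr2 by 1.93 ± 0.507, Ier3 by 2.36 ± 0.632, adjusted p = 0.0695 with the block) and lipid and retinoid genes in 1 of 16 (Crabp2 by 5.38 ± 1.13, adjusted p = 0.0529 with the CellBender counts). Pdgfra, the receptor gene used for the Cre driver, was at 431 ± 16.6 CPM against 516 ± 59 and Pdgfrb at 221 ± 69.6 against 137 ± 5.9, neither called (adjusted p = 0.553 and 0.186).

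**Figure D2:**
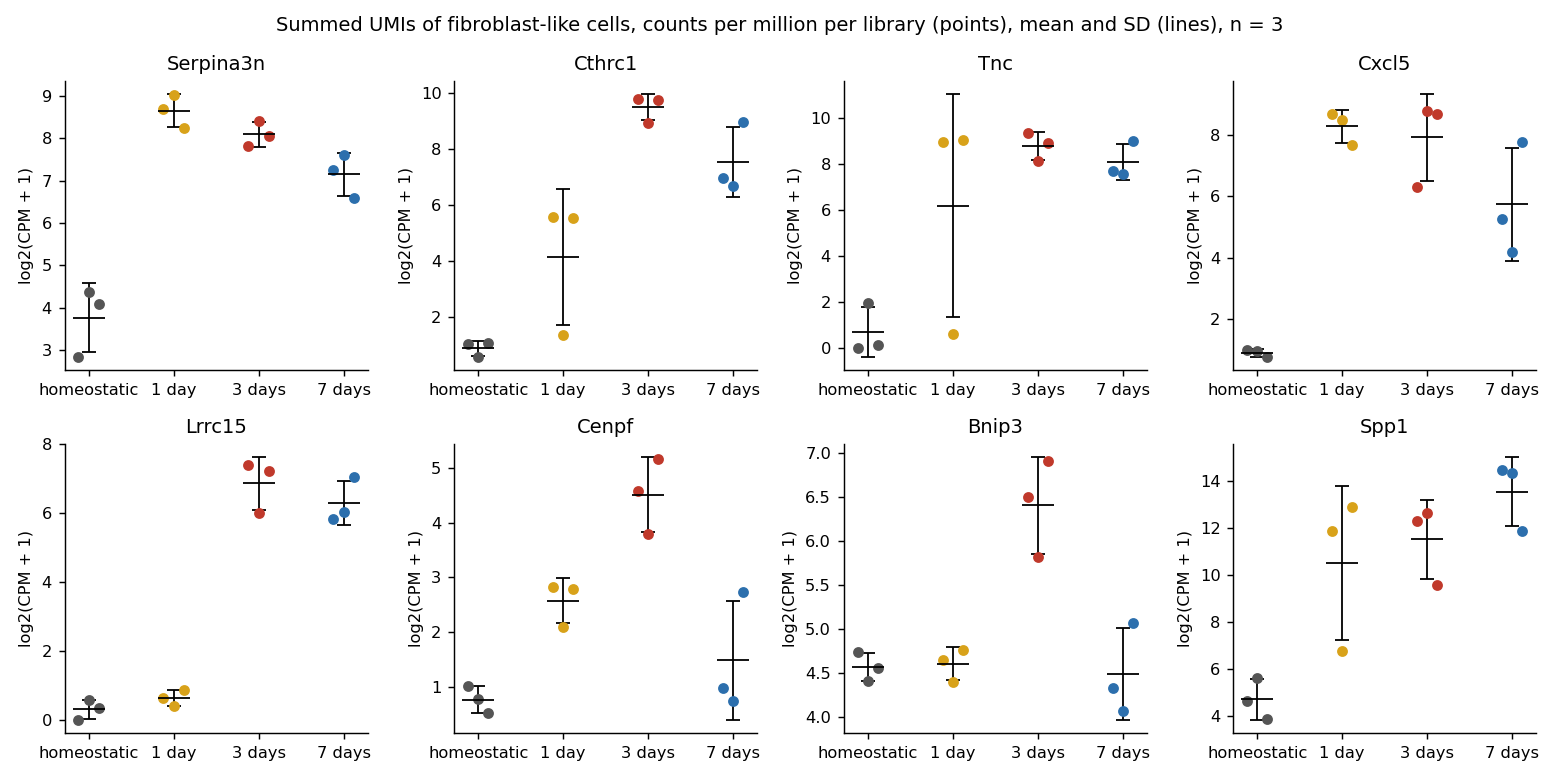
Log2(CPM + 1) of 8 genes in the summed fibroblast-like cells (vertical axes) by group (horizontal axes); points are libraries, lines the mean and SD of 3 libraries. Cthrc1 averages 0.856 CPM in the homeostatic group and 745 at day 3, and Bnip3 averages 87.6 CPM at day 3 and 22.4 at day 7.

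At day 7, Spp1 in fibroblast-like cells rose over the homeostatic group by 9.59 ± 1.62 (adjusted p = 0.0156), from 28.5 ± 17.8 to 15900 ± 10600 CPM (SD, n = 3). The fold rests on 7-day replicates 1 and 2 (23150 and 20820 CPM), since the annotation term takes up replicate 3 (3734 CPM). The same holds for the other day-7 folds against homeostatic, and with the CellBender counts only replicate 1 remains. Kif26b rose by 8.43 ± 1.44, the latent TGF-beta binding protein Ltbp2 by 7.47 ± 1.66 and Cthrc1 by 7.00 ± 1.19 (adjusted p = 0.0159, 0.0352 and 0.0159). The proteoglycan Spock2 (-2.98 ± 0.701), Ccser1 (-2.84 ± 0.533), the Wnt amplifier Rspo3 (-2.77 ± 0.477) and adrenomedullin Adm (-2.44 ± 0.425) fell. In all 582 genes were called, 376 higher and 206 lower, of 14716. The CellBender counts gave 91, without Ltbp2, Cthrc1, Spock2, Ccser1, Rspo3 and Adm (adjusted p = 0.052 to 0.228), and the 8 libraries with Ensembl-named features 1229, and leaving out 7-day replicates 1 or 2 left 49 and 69. Without homeostatic replicates 1, 2 or 3 the count was 168, 77 and 82, and without 1-day replicate 2 it was 1437. Cluster 4 held 63.8% of these cells (31.6% to 80.7% between libraries).

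Of the fixed lists, 6 of 14 matricellular genes rose and 1 fell at day 7 (Thbs2 by 1.75 ± 0.287), 6 of 15 TGF-beta pathway genes rose (Inhba by 2.99 ± 0.484), as did 5 of 13 collagens (Col16a1 by 1.69 ± 0.22, Col12a1 by 3.34 ± 0.515), 3 of 18 crosslinking genes (Loxl1 by 2.22 ± 0.287), 2 of 12 contractile genes (Lrrc15 by 7.58 ± 0.595, Tpm1 by 1.14 ± 0.223) and 1 of 16 proteases and inhibitors (Timp1 by 5.41 ± 0.867). Adjusted over the list alone, 10, 8, 7, 10, 6 and 8 members of these lists were higher. The crosslinking gene P4ha3 stood at 3702 UMIs against 3, a ratio of 144 (exact interval 49.2 to 698). Mitosis (median 1.37) and basement membrane genes (median -0.426) passed camera with no member called. None of these 8 lists kept its call with an estimated correlation, where the lowest adjusted p was 0.165. In lists that did not pass, Nrg1 rose by 4.84 ± 0.992, Mfap5 by 2.24 ± 0.481, Irf7 by 1.27 ± 0.276, Ldha by 1.38 ± 0.304 and Cxcl5 by 5.06 ± 0.853, and Ccl11 fell (-2.32 ± 0.457). With the CellBender counts Inhba, Tpm1, P4ha3, Nrg1, Mfap5, Irf7, Ldha, Cxcl5 and Ccl11 lost their call (adjusted p = 0.0563 to 0.176). Acinar markers were called lower in 5 of 10 cases, ductal in 4 of 8 and erythroid in 2 of 5. Pdgfra was at 463 ± 147 CPM and Pdgfrb at 320 ± 90.8 (adjusted p = 0.914 and 0.0561).

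**Figure D3:**
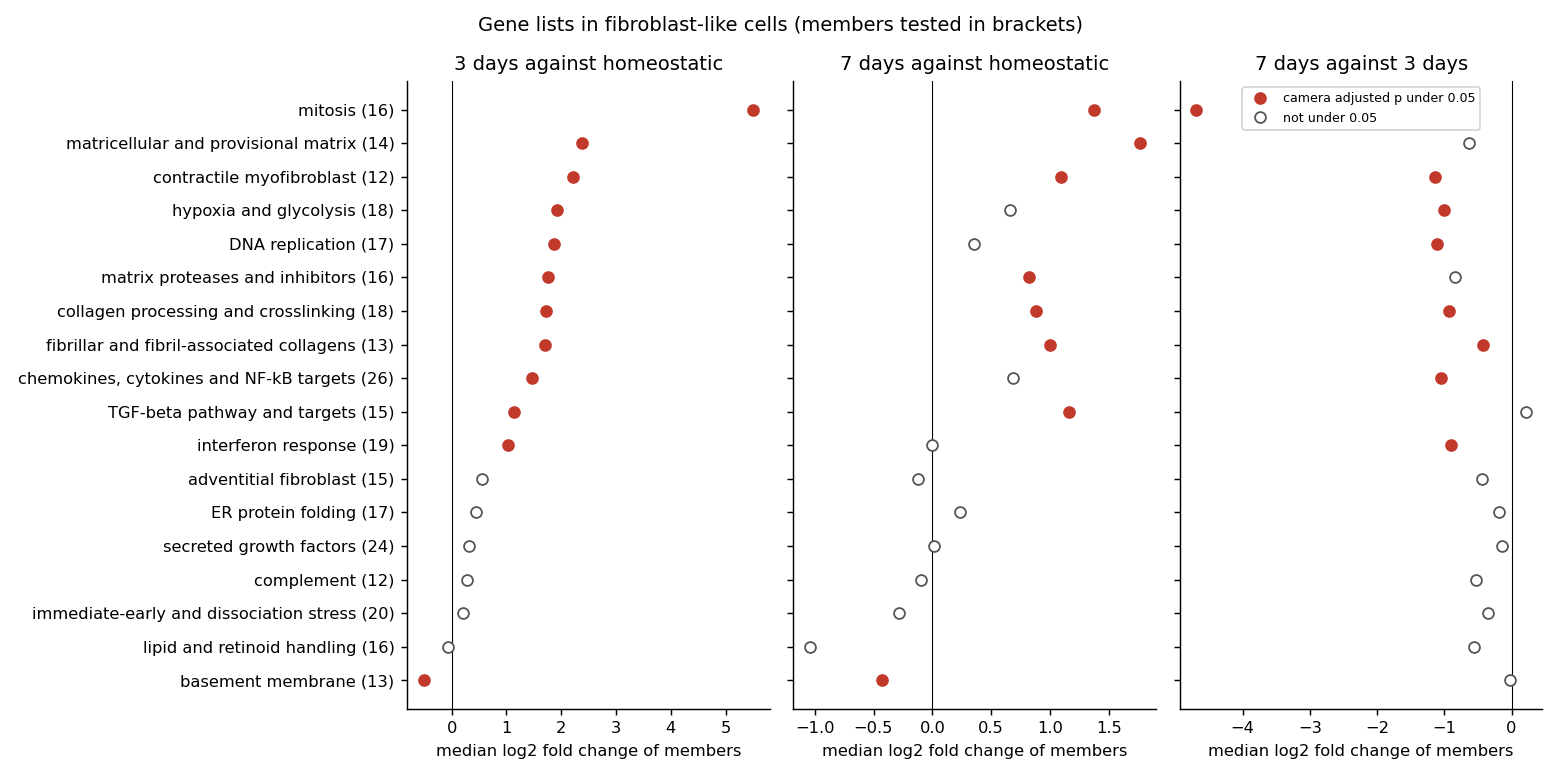
Median log2 fold change of the members of each of 18 gene lists in fibroblast-like cells (horizontal axes) for day 3 and day 7 against homeostatic and day 7 against day 3; filled points have a camera adjusted p under 0.05. Mitosis genes have a median of 5.50 at day 3 and of -4.69 from day 3 to day 7.

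Direct comparisons asked how fibroblast-like cells differed between the days. From day 1 to day 3, Lrrc17 rose by 6.08 ± 0.728 (adjusted p = 0.00633), the collagen Col24a1 by 5.78 ± 0.782 and the Wnt modulator Sfrp2 by 5.67 ± 0.84. Through the annotation term, these folds also take in the difference of 7-day replicate 3 from 7-day replicates 1 and 2. Lrrc17 stood at 14.2, 21.2 and 8.35 CPM in 1-day replicates 1 to 3 and at 227, 144 and 375 in those of day 3. In 7-day replicate 3 it stood at 214, against 47.1 and 60.9 in 7-day replicates 1 and 2. The same 7-day values were 98.0 against 20.6 and 42.7 for Col24a1 and 747 against 168 and 259 for Sfrp2. The ER chaperones Dnajb9 (-1.75 ± 0.318) and Cnpy3 (-1.71 ± 0.284) and the mitochondrial peptidase Immp2l (-1.60 ± 0.336) fell. Mitosis genes rose in 8 of 16 cases, contractile genes in 6 of 12 and collagens in 4 of 13, and these 3 lists also passed camera with an estimated correlation (adjusted p = 0.0493, 0.0493 and 0.012). Adjusted over the list alone the counts were 15, 7 and 8. With the shift taken out in place of the term, no list passed with an estimated correlation, the lowest adjusted p being 0.198. The CellBender counts gave 2 calls, neither of them Lrrc17, Col24a1, Sfrp2, Dnajb9, Cnpy3 or Immp2l (adjusted p = 0.0597 to 0.193). There the annotation term rests on 7-day replicates 2 and 3 against 7-day replicate 1, so these losses cannot be assigned to free RNA. Of 14716 genes 188 were called, 182 higher and 6 lower; without the annotation term the count was 2424. Leaving out 7-day replicates 1 or 2 left 6 and 1, without 1-day replicate 3 the count was 100, and without 1-day replicate 2 it was 1136.

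From day 3 to day 7 the mitosis genes fell. All 16 mitosis genes had lower values, 14 of them called, with a median of -4.69, and this list kept its call with an estimated correlation (adjusted p = 0.039). Hypoxia and glycolysis genes fell in 3 of 18 cases and crosslinking genes in 4 of 18, and both lists lost their call there (adjusted p = 0.273 with an estimated correlation for both). Adjusted over the list alone, 16 mitosis, 7 hypoxia and 8 crosslinking genes were lower. Folds from day 3 to day 7 rest on 7-day replicates 1 and 2, and with the CellBender counts on replicate 1 alone. In 7-day replicates 1 to 3 Ube2c stood at 0.877, 0.564 and 7.99 CPM, against 27.7, 18.2 and 47.3 in those of day 3. Cenpf stood at 0.968, 0.689 and 5.625 CPM, against 22.97, 12.85 and 34.71. Replicate 3 thus fell less than the folds show. The mitophagy gene Bnip3 (-2.33 ± 0.301), the hyaluronan synthase Has2 (-2.59 ± 0.506) and the fatty acid binding Fabp5 (-2.40 ± 0.348) fell, and Igfbp5 (2.54 ± 0.369), Prss12 (2.38 ± 0.417) and Ncald (1.90 ± 0.311) rose. Of the 158 genes called, 25 were higher and 133 lower. With the replicate number as a block 67 were called, 66 of them among the 158, and Has2, Prss12 and Ncald lost their call (adjusted p = 0.0893, 0.072 and 0.0628). From the CellBender counts edgeR called 0 (1994 at an unadjusted p), and Bnip3, Has2, Fabp5, Igfbp5, Prss12 and Ncald had adjusted p = 0.258 to 0.303. Within the libraries of Ensembl-named features 305 were called, 153 of them among the 158. These hold the same 7-day replicates 1 and 2 that the main fit rests on, so the overlap is no independent check. Without the annotation term or with the shift taken out, where 7-day replicate 3 enters, 0 were called by edgeR (2080 and 2026 at an unadjusted p). DESeq2 called 835 with the term. Leaving out 7-day replicates 1 or 2 left 0 calls, without any 1 homeostatic library or 3-day replicate 3 the count was 71 to 75, and without 1-day replicate 2 it was 464.

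From day 1 to day 7, the fit with the annotation term sets 7-day replicate 3 alone against the libraries of day 1, so the spread within day 7 does not enter. Lrrc15 rose by 7.81 ± 0.504, from 0.541, 0.308 and 0.82 CPM in 1-day replicates 1 to 3 to 129.5 in that library. Lrrc15 and Fgfr2 (2.20 ± 0.283) were picked for their difference between the days. In all, 122 genes were called, 118 higher and 4 lower. Collagens rose in 3 of 13 cases and passed camera with an estimated correlation (adjusted p = 0.0113), which no list did with the shift taken out (lowest adjusted p = 0.263), and 1 of 17 ER protein folding genes fell, with a median of -0.974 over the list (adjusted p = 0.12 with an estimated correlation). Adjusted over the list alone, 8 collagens were higher and 10 ER genes lower. Over all 4 groups 1549 genes differed. Without the annotation term 2041 and 4374 genes were called, and the first count was 43 without 1-day replicates 1 or 3 and 1573 without 1-day replicate 2. Leaving out homeostatic replicates 1 or 2 or 7-day replicates 1 or 2 gave 63 to 78. For all 4 groups the count was 509 to 800 without any 1 homeostatic library or 7-day replicates 1 or 2, and 4272 without 1-day replicate 2.

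Other stromal classes were compared with the homeostatic group as context. In endothelial-like cells at day 3, Apln, the apelin ligand of sprouting vessels, rose by 5.16 ± 0.586 (adjusted p = 0.00179), Timp1 by 4.99 ± 0.761 and the aggrecanase Adamts4 by 5.97 ± 1.05, whose share of counts also moves by 0.615 between annotations. The epithelial genes Fxyd2 (-7.57 ± 1.87), Scgb1b27 (-6.41 ± 2.01) and Scgb2b27 (-6.34 ± 1.85) fell here as well, the last 2 without a call under the block (adjusted p = 0.124 and 0.102) or with the CellBender counts (adjusted p = 0.0622 and 0.0538). Timp1 stood at 3.60 and Fxyd2 at -8.25 with the CellBender counts. All 16 mitosis genes and 15 of 17 DNA replication genes rose, and 8 of 20 immediate-early genes fell (adjusted p = 0.159, 0.229 and 0.245 with an estimated correlation); adjusted over the list alone, 16 and 15 of the first pair were higher. In all 3167 of 13577 genes were called at day 3 (1848 higher), 542 at day 7 (407 higher) and 0 at day 1 (1671 at an unadjusted p; 131 by DESeq2). At day 7 Spsb1 rose by 4.40 ± 0.836 and D5Ertd615e by 3.54 ± 0.454, while Rnd3 (-2.98 ± 0.575), Cyp4b1 (-2.56 ± 0.296) and Sncg (-2.31 ± 0.497) fell. Timp1 rose by 3.67 ± 0.774 at day 7. With the CellBender counts 2 genes were called at day 7, Timp1 stood at -0.48, and none of these 6 genes kept its call (adjusted p = 0.174 to 0.934). For day 7 the CellBender fit rests on 7-day replicate 1 alone, so these losses cannot be assigned to free RNA. Cluster 0 held 63.7% of the homeostatic endothelial-like cells, and cluster 1 held 38.4% of those of day 3 (4.83% to 63.7% between libraries) and 32.8% of those of day 7. Without homeostatic replicates 1, 2 or 3 the counts were 1437, 1088 and 1621 at day 3 and 6, 2 and 16 at day 7, and without 3-day replicates 2 or 3 they were 2085 and 1430 and 123 and 822. The day-7 count was 1 without 7-day replicate 2, 163 and 949 without 1-day replicates 1 and 2 and 290 without 3-day replicate 1, and the day-1 count was 283 without 1-day replicate 2.

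The sums of mural-like cells held 0 Spp1 UMIs in the homeostatic group, 786 at day 3 and 1957 at day 7, at least 277-fold and 803-fold higher against a floor of 3 counts over the group. These UMIs can include free RNA: at day 7 Spp1 stood at 474 CPM here and at 15900 in fibroblast-like cells, and it rose by 8.90 ± 1.42 in endothelial-like cells. The Spp1 call was lost with the CellBender counts (adjusted p = 0.112 at day 3 and 0.87 at day 7) and, at day 3, with the block (adjusted p = 0.0651). These lost calls do not by themselves show free RNA, and for day 7 the CellBender fit rests on 7-day replicate 1 alone. At day 3 Timp1 rose by 7.18 ± 1.35 and Tnfaip2 by 5.63 ± 1.10 (7.46 with the CellBender counts), while the mitochondrial protein gene Chchd10 (-3.56 ± 0.42), the potassium channel Kcnma1 (-3.38 ± 0.618) and Fxyd2 (-5.18 ± 1.11) fell. Of 19 interferon response genes 18 rose at day 3 (18 adjusted over the list alone; adjusted p = 0.197 with an estimated correlation), and of 11 contractile genes 4 fell and 1 rose (adjusted p = 0.276 with an estimated correlation). At day 7 Rgs16 rose by 5.07 ± 0.965 and Timp1 by 6.43 ± 1.42, and Timp4 (-4.07 ± 0.602), the purinergic receptor P2rx1 (-3.97 ± 0.968) and Fxyd2 (-5.02 ± 1.31) fell. With the CellBender counts 13 genes were called at day 7, and none of these 5 (adjusted p = 0.0967 to 0.402). Of 10659 genes 1530 were called at day 3, 1131 at day 7 and 0 at day 1 (1573 at an unadjusted p; 136 by DESeq2). No list of the endothelial-like or mural-like cells kept its camera call with an estimated correlation at day 3, where the lowest adjusted p was 0.15 and 0.197. Without homeostatic replicates 1, 2 or 3 the day-3 count was 558, 611 and 969, and without 3-day replicate 3 it was 589. The day-7 count was 267 and 272 without homeostatic replicates 1 and 2 and 676 and 5 without 7-day replicates 1 and 2, and the day-1 count was 111 without 1-day replicate 2. Cluster 31 held 50.0% of the homeostatic mural-like cells and cluster 20 held 69.4% of those of day 3 and 66.0% of those of day 7.

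Macrophage-, monocyte- or dendritic-like cells at day 3 had 2836 UMIs of the interferon-induced Ifitm1 against 1 in the homeostatic group, a ratio of 2203 (exact interval 395 to 87050). They had 442 UMIs of the matrix protein Emilin2 against 3 in the homeostatic group, a ratio of 115 (exact interval 38.9 to 557), and Timp1 rose by 5.32 ± 0.895. The interferon-induced chemokine Cxcl9 (-5.44 ± 0.813) and Bpgm (-4.92 ± 0.935) fell. Lyz1 fell too (-3.50 ± 0.728), and its share of counts moves by 4.09 between annotations. In this class 164 of 11077 genes were called at day 3, 1 at day 7 (Slc25a37, a mitochondrial iron transporter, at -3.48 ± 0.456, named after its value was seen) and 0 at day 1 (868 at an unadjusted p; 18 by DESeq2). At day 3 the CellBender counts gave 8 calls, none of them these 6 genes (adjusted p = 0.0575 to 0.589), and the block gave 430. Without homeostatic replicates 1 or 2 the day-3 count was 1, without homeostatic replicate 3 305, without 3-day replicates 2 or 3 13, without 1-day replicate 3, 3-day replicate 1 or 7-day replicates 1 or 2 it was 52 to 78, and without 1-day replicate 2 it was 1062. Without 1-day replicate 2 the counts of days 1 and 7 were 248 and 230. Cluster 9 held 74.2% of the homeostatic cells of this class and cluster 23 held 40.1% of those of day 3 (23.5% to 66.2% between libraries). Ifitm1 was also among the leading genes of neutrophil-like cluster 18, a class absent from the homeostatic libraries, so RNA of neutrophils can enter its ratio. The erythroid marker Hbb-bs was among the leading genes of macrophage-like clusters 9 and 26, so erythroid RNA can enter these sums. Whether Bpgm or Slc25a37 followed it was not tested.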

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

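The tests of the annotation difference and of the quality of the named fibroblast-like cells were chosen only after the results they address were seen. Each result here is a difference between days in the change of a gene from the homeostatic group, tested directly in fibroblast-like cells with edgeR, or a signal in cells outside the named classes. From day 1 to day 3, Lrrc15 differed by 8.88 (log2; adjusted p = 0.000531), Ube2c by 6.29 (adjusted p = 0.00247), Cenpf by 4.97 (adjusted p = 0.00864), Mmp23 by 3.85 (adjusted p = 0.00239) and P4ha2 by 3.31 (adjusted p = 0.0165). Through the annotation term, differences from day 1 to day 3 take in that of 7-day replicate 3 from 7-day replicates 1 and 2. Ube2c stood at 5.45, 4.31 and 3.50 CPM in 1-day replicates 1 to 3 and at 27.7, 18.2 and 47.3 in those of day 3. In 7-day replicate 3 it stood at 7.99, against 0.877 and 0.564. Cenpf stood at 6.13, 3.28 and 5.89 CPM at day 1 and at 23.0, 12.9 and 34.7 at day 3. Its 7-day values were 5.63 against 0.968 and 0.689. Bnip3 differed by 2.80 (adjusted p = 0.0134), Tpm1 by 2.50 (adjusted p = 0.00994) and Fgfr2 by 1.81 (adjusted p = 0.0368). Of these 8 only Lrrc15 kept its call with the CellBender counts (adjusted p = 0.0347, against 0.0754 to 0.243 for the others). The annotation term rests there on 7-day replicates 2 and 3 against 7-day replicate 1, so these losses cannot be assigned to free RNA. From day 3 to day 7, Ube2c differed by -5.45 and Cenpf by -4.84 (adjusted p = 0.00476 for both), Cxcl5 by -3.49 (adjusted p = 0.0494), Bnip3 by -2.33 (adjusted p = 0.00844), Adm by -2.23 (adjusted p = 0.0345) and Hif1a by -2.16 (adjusted p = 0.0289). P4ha2 differed by -2.15 (adjusted p = 0.0268), Mmp23 by -1.24 (adjusted p = 0.0475) and Tpm1 by -1.21 (adjusted p = 0.0384). With the replicate number as a block Adm, Cxcl5, Hif1a, Mmp23 and Tpm1 lost their call (adjusted p = 0.0733 to 0.174), and with the CellBender counts all 9 did (adjusted p = 0.258 to 0.364). From day 1 to day 7, Lrrc15 differed by 7.81 and Fgfr2 by 2.20, where 7-day replicate 3 alone stands for day 7. The share of counts of Fgfr2 moves by -2.33 between the annotations within a single library. From day 3 to day 7 edgeR made 0 calls over the 12 libraries without the annotation term (2080 at an unadjusted p), and DESeq2 made 835 with the term. In the 8 libraries of Ensembl-named features, which need no term, edgeR made 305, from the same 7-day replicates 1 and 2 as the main fit.

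Unnamed clusters 19 and 22, whose best marker list was that of fibroblasts (11 and 8 markers up), held 3759 cells of 3-day replicate 3 (25.6% of that library) and 0 homeostatic cells. They stayed unnamed because their leading genes held 1 marker of another class, Ndufa4l2 of the mural list, and 0 of fibroblasts. They may thus be fibroblasts left out by the naming rule. With the unnamed clusters added to the fibroblast-like class 1883 genes were called at day 3, 1808 of them among the 2131. In the same library the hypoxia and glycolysis genes of the named fibroblast-like cells stood above the other 3-day libraries by a median log2 difference of 0.469. Cells of low quality stay open. The median mitochondrial percentage of the named cells was 0.586 times that of the higher of the other 3-day libraries (1.76% against 3.01%, and 2.01% in the lower), but its upper quartile of 2.23% lay above the lower median, and these cells held fewer genes (3450 against 4156 and 3947). The unnamed clusters, at 0.572 times the percentage of the named cells (1.01% against 1.76%), say nothing about the named ones; they held 2001 genes. A state of the whole preparation, such as delay before dissociation, stays open too: the list stood higher by 0.510 in endothelial-like cells, with 15 of 18 members higher, by 0.439 in macrophage-like cells, also with 15 of 18, and by -0.02 (-0.02406) in mural-like cells, with 7 of 15 higher. A biological difference of this mouse was not tested.

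Without an annotation term 3557 genes were called from the homeostatic group to day 1 in fibroblast-like cells, against 13 with it. The annotation difference as the whole cause is argued against, since a share of 0.873 of these genes was called with the same sign once the measured shift was taken out. Another difference between the symbol-named libraries and the rest cannot be told apart from the change at day 1: the fitted change with the term was a median of 0.885 times that without it (quartiles 0.649 and 1.11), and 7-day replicate 3 alone links the annotations. The calls ended largely with the error, whose median rose from 0.323 to 0.545, while the median size of the change went from 1.32 to 1.12 and 97.0% of the genes kept their sign. The effect of ligation itself stays open as the biological explanation, untested.

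Acinar and ductal genes fell in fibroblast-like cells after ligation. A change within fibroblasts is argued against, because the 12 markers tested in 3 classes fell by a median of -6.30 (-6.297) at day 3 in endothelial-like cells, against -6.46 in fibroblast-like and -6.21 in mural-like cells. Free RNA from acinar and ductal cells could account for the fall: the classes differed by a median of at most 0.634 in either comparison, a test that could have come out otherwise. It is not shown to be the cause. With the CellBender counts at day 3, epithelial genes outside these markers stayed low in fibroblast-like cells. Scgb1b27 went from -6.64 to -8.14, Scgb2b27 from -6.55 to -8.17, Prol1 from -4.74 to -5.54 and Fxyd2 from -6.26 to -5.80. The 12 markers were read from the main counts only. Loss of acinar and ductal cells and their depletion before sequencing were not separated.

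Other splits of the libraries were counted for each number of genes called. Over all 4 groups 1 of 100 splits, the real one, called as many as 1549 genes, and the highest other called 1088. That other split keeps the 3 homeostatic libraries together. The share of splits is under the 0.05 set in advance, which argues against chance but does not exclude it. Only 100 splits were counted, and libraries with correlated deviations are not freely exchangeable. Of the splits that part all 3 pairs of equal replicate number, those other than the real one called 0 genes with edgeR for day 3 against homeostatic in all 4 classes and for day 7 against day 3. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In fibroblast-like cells the real and the highest other split called 13 and 0 genes for day 1 against homeostatic, 2131 and 0 for day 3, 582 and 0 for day 7, 188 and 180 for day 3 against day 1, and 158 and 12 for day 7 against day 3; in each, 1 split called as many. For day 7 against day 1 they called 122 and 660, and 2 splits called as many; the larger one groups 1-day replicates 1 and 3 with 7-day replicate 1, which points to a structure of the samples. At days 1, 3 and 7 the pairs were 0 and 78, 164 and 1, and 1 and 0 in macrophage-like cells, 0 and 0, 3167 and 1, and 542 and 0 in endothelial-like cells, and 0 and 1, 1530 and 0, and 1131 and 1 in mural-like cells; all 10 splits reach the counts of 0, and 1 each of the others.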

How the results depend on the processing

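The alternatives with the shift taken out, 2 libraries that stand apart left out, the 8 libraries with Ensembl-named features alone, equal cells per library, the dendritic cluster left out and another denominator were chosen after seeing the data. Of the counts of calls, 306 stayed within 1.5 times under alternatives fixed in advance and 164 did not, and 47 and 42 under added ones. Of the values of named genes under alternatives fixed in advance 2129 kept their direction and side of the threshold, 456 lost the call, 10 gained it and 7 changed sign; under added ones 471, 56, 7 and 1. For gene lists 1122 kept theirs, 129 lost it and 1 changed sign under alternatives fixed in advance, and 230, 13 and 1 under added ones. For shares 191 kept theirs, 21 lost it and 4 gained it under alternatives fixed in advance, and 28, 2 and 1 under added ones. Of the 39 genes named for fibroblast-like cells at day 3, 23 were called in every alternative, of the 24 at day 7, 3, and of the 4 at day 1, 0; of the 6 each for day 3 against day 1 and day 7 against day 3, 0. In endothelial-like cells these counts were 3 of 6 at day 3 and 0 of 6 at day 7, in mural-like cells 4 and 0, and in macrophage-like cells 0 of 6 at day 3. The median log2 change of all genes against homeostatic was at most 0.0393 with TMM and 0.0383 with RLE scaling. Unless said otherwise, the cause was not tested. The shallowest fibroblast sums were those of homeostatic replicates 1 and 2 (904177 and 4035397 UMIs), which limits genes of few counts there, although replicates of every group differed by more than counting noise. Drawing 150 cells per library removes counts by construction.

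In fibroblast-like cells, day 1 against homeostatic gave 13 calls. DESeq2 gave 453, CellBender counts 0, no annotation term 3557, doublets kept 5, the shift taken out 3224, 2 libraries left out 2928 and equal cells 2. Leaving out 1 library gave 0 (homeostatic replicate 1) to 2051 (1-day replicate 2). Day 3 against homeostatic (2131) gave 787 with equal cells and 678 to 3353 without 1 library. Day 7 against homeostatic (582) gave 1358 with DESeq2, 91 with CellBender counts, 2144 in only the 6 libraries compared, 2104 with 2 libraries left out, 1229 with Ensembl-named features alone, 193 with equal cells and 49 to 1437 without 1 library. Day 3 against day 1 (188) gave 613 with DESeq2, 2 with CellBender counts, 2424 without the annotation term, 286 with doublets kept, 1947 with the shift taken out, 1508 with 2 libraries left out, 29 with equal cells and 1 to 1136 without 1 library. Day 7 against day 3 (158) gave 835 with DESeq2, 0 with CellBender counts, 0 without the annotation term and 0 with the shift taken out (edgeR, 2080 and 2026 at an unadjusted p in the last pair), 69 in only the 6 libraries compared, 396 with doublets kept, 79 with classes from each library alone, 339 with 2 libraries left out, 305 with Ensembl-named features alone, 6 with equal cells and 0 to 464 without 1 library. Day 7 against day 1 (122) gave 537 with DESeq2, 444 with CellBender counts, 2041 without the annotation term, 24 in only the 6 libraries compared, 1842 with the shift taken out, 2474 with 2 libraries left out, 48 with equal cells and 43 to 1573 without 1 library. Any difference between the 4 groups (1549) gave 3453 with DESeq2, 4374 without the annotation term, 4012 with the shift taken out, 4289 with 2 libraries left out, 2849 with Ensembl-named features alone, 519 with equal cells and 509 to 4272 without 1 library. Without 7-day replicate 3, comparisons with day 1 could not be estimated, and only the 6 libraries compared gives no value for day 1 against homeostatic or day 3 against day 1, because annotation and group coincide there. With CellBender counts, day 7 against homeostatic or day 3 rests on 7-day replicate 1 alone. Day 7 against day 1 then rests on 7-day replicates 2 and 3. For the other comparisons with day 1, the annotation term then rests on 7-day replicates 2 and 3 against 7-day replicate 1. These counts thus also reflect a change of libraries.

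In macrophage-like cells, day 1 (0 calls) gave 18 with DESeq2, 5 with no filter, 2062 without the annotation term, 1933 with the shift taken out, 476 with 2 libraries left out and 0 to 248 without 1 library. Day 3 (164) gave 1182 with DESeq2, 548 with no filter, 8 with CellBender counts, 272 with the shift taken out, 743 with 2 libraries left out, 753 with Ensembl-named features alone, 272 with the dendritic cluster left out and 1 to 1062 without 1 library. Day 7 (1) gave 166 with DESeq2, 69 with no filter, 0 with CellBender counts, 14 without the annotation term, 15 with the shift taken out, 317 with 2 libraries left out, 186 with Ensembl-named features alone, 5 with the dendritic cluster left out and 0 to 230 without 1 library. In endothelial-like cells, day 1 (0) gave 131 with DESeq2, 2457 without the annotation term, 1992 with the shift taken out, 760 with 2 libraries left out and 0 to 283 without 1 library; day 3 (3167) gave 1088 to 3681 without 1 library. Day 7 (542) gave 1650 with DESeq2, 351 with no filter, 2 with CellBender counts, 1600 without the annotation term, 1708 with the shift taken out, 1963 with 2 libraries left out, 830 with Ensembl-named features alone and 1 to 949 without 1 library. In mural-like cells, day 1 (0) gave 136 with DESeq2, 63 with no filter, 1 with CellBender counts, 2362 without the annotation term, 2162 with the shift taken out, 290 with 2 libraries left out and 0 to 111 without 1 library. Day 3 (1530) gave 892 with 2 libraries left out and 558 to 1735 without 1 library, and day 7 (1131) gave 13 with CellBender counts, 1880 without the annotation term, 1963 with the shift taken out, 1847 with 2 libraries left out and 5 to 1517 without 1 library.

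The replicate block, with the replicate number as a term, gave 0 calls for day 1 against homeostatic, 342 for day 7 against homeostatic, 17 for day 3 against day 1, 67 for day 7 against day 3 and 30 for day 7 against day 1 in fibroblast-like cells. It gave 2, 430 and 3 in macrophage-like cells at days 1, 3 and 7 and 0 classes of cells by share, and it moved no other count of calls by over 1.5 times. Over all pairs of groups, 10 of 18 correlations of deviations between libraries of the same number were over 0.1 (-0.238 to 0.396), and 7 of 12 libraries correlated best with their own number.

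Camera with an estimated correlation called 0, 0, 0, 3, 1 and 1 gene lists for day 1, day 3 and day 7 against homeostatic, day 3 against day 1, day 7 against day 3 and day 7 against day 1, where the preset correlation called 10, 12, 8, 8, 8 and 8. Fry called 1 for day 1 against homeostatic and 5, 3 and 3 for the comparisons between days. The fibrillar collagen list at day 1 changed direction without the annotation term (adjusted p = 0.626) and with the shift taken out (adjusted p = 0.63). Timp1 in endothelial-like cells at day 7 was -0.48 with CellBender counts. Pdgfra in fibroblast-like cells, not called in any comparison, was 0.30 with CellBender counts and 0.01 (0.0121) with doublets kept at day 7 against homeostatic. Without 1 library it was -0.60 to 0.32 there, -0.21 to 0.69 at day 1 against homeostatic and -0.34 to 0.59 from day 3 to day 7. Pdgfrb from day 1 to day 7 was 0.08 (0.0795) without the annotation term and 0.09 (0.0858) with the shift taken out. The number of classes whose share differed (2) was 0 with classes from each library alone, 0 with Ensembl-named features alone (280 assignments) and 0 to 3 without 1 library.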

Other observations

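Of the tests in this part, those with the measured annotation shift taken out and those of the macrophage-, monocyte- or dendritic-like class, put together after the data were seen, were not planned, and neither were the counts of list members with the CellBender counts. In mural-like cells, the pericytes and smooth muscle around vessels, several gene groups rose. At day 3, 18 of 19 interferon response genes rose with a median of 2.23, 12 of 13 DNA replication genes and 11 of 15 mitosis genes rose, and 11 of 13 collagens and 10 of 13 basement membrane genes rose (camera; adjusted p = 0.197 with an estimated correlation for each). With the CellBender counts these were 18, 12, 14, 9 and 9. Contractile genes, which smooth muscle uses for tension, fell in 4 of 11 cases with 1 higher at day 3 (adjusted p = 0.276 with an estimated correlation) and in 6 of 11 with 1 higher at day 7 (adjusted p = 0.291 with an estimated correlation); at day 7 the CellBender counts gave 13 calls in all, none of them in this list. With the shift taken out at day 1, 16 of 19 interferon response genes rose and 6 of 11 contractile genes fell with 1 higher (adjusted p = 0.349 with an estimated correlation for both). The ankyrin repeat gene Asb2 (-4.33 ± 0.708) and phospholamban Pln (-4.26 ± 1.06) fell there, and Tnc rose by 4.57 ± 1.05. Cluster 31 held 50.0% of the homeostatic and 6.23% of the day-1 mural-like cells, and cluster 20 held 25.7% (0.602% to 38.4% between libraries) and 57.4%.

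Endothelial-like cells at day 3 had 12 of 13 collagens higher (adjusted p = 0.253 with an estimated correlation), 13 of 17 crosslinking genes higher (adjusted p = 0.244 with an estimated correlation) and 8 of 13 basement membrane genes higher (adjusted p = 0.15 with an estimated correlation). Free RNA can enter these sums: with the CellBender counts 2 of the 5 collagens tested, 5 of 14 crosslinking genes and 9 of 12 basement membrane genes were called higher. At day 7, 6 of 13 basement membrane genes rose (adjusted p = 0.132 with an estimated correlation), none of them among the 2 genes called with the CellBender counts. For day 7 the CellBender fit rests on 7-day replicate 1 alone, so these lost calls do not show free RNA. With the shift taken out at day 1, the activin subunit Inhbb rose by 4.50 ± 0.742 and the growth factor Igf1 fell (-3.27 ± 0.352). Cluster 0 held 63.7% of the homeostatic and 12.5% of the day-1 cells of this class (0.079% to 37.0% between the day-1 libraries), and cluster 1 held 0.82% and 44.4% (7.02% to 63.9%). In macrophage-like cells at day 1 with the shift taken out, the chitinase-like Chil3 had 36229 UMIs against 0, at least 3005-fold higher against a floor of 3 counts over the group, Vcan rose by 8.25 ± 1.49 and Cxcl9 fell (-3.88 ± 0.696). Cluster 9 held 74.2% of the homeostatic and 48.7% of the day-1 cells of this class (30.8% to 83.7% between the day-1 libraries), and cluster 23 held 2.29% (0.236% to 4.98%) and 33.5% (5.19% to 48.7%). In its sums at day 3, 3 of 11 collagens were called higher (adjusted p = 0.495 with an estimated correlation). With the CellBender counts 4 collagens were tested there and none was called, and Timp1 stood at 2.09 (adjusted p = 0.589) against 5.32.

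Markers of other cell types in the fibroblast sums, besides acinar, ductal and erythroid ones, were tested as lists. At day 1 with the annotation term the 12 fibroblast markers had a median of -0.90 (-0.899), 0 of them called, and the list passed camera (adjusted p = 0.00199). The fibrillar collagen list, which shares members with it, changed direction at day 1 with the shift taken out. Marker lists were not tested with an estimated correlation. At day 3, 1 of 7 dendritic markers was lower and 1 of 10 T, NK or innate lymphoid markers higher, and both lists passed camera (adjusted p = 0.0276 and 0.0424). The neutrophil (adjusted p = 0.0711), neuron (0.0579), blood endothelial (0.0979), lymphatic endothelial (0.162), fibroblast (0.481), Schwann (0.483), mural (0.532), myoepithelial (0.574), macrophage or monocyte (0.852) and B or plasma (0.971) lists did not. Mast, adipocyte, platelet and skeletal muscle lists had no result there.

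The tdTomato transcript was read as values only. Per 10000 UMIs of fibroblast-like cells it ran from 0.187 in 7-day replicate 1 to 16.4 in 7-day replicate 2, and it was higher there than in endothelial-like cells in 9 of 12 libraries. In 7-day replicate 1 it was 0.187 in fibroblast-like, 0.540 in endothelial-like and 0.815 in mural-like cells, and 0.186, 0.547 and 0.837 in the CellBender matrix. In homeostatic replicate 1 it was 10.98 in fibroblast-like and 11.7 in endothelial-like cells. In homeostatic replicate 2 it was 12.0 and 12.3 in the main matrix, and 11.4 and 0.647 in the CellBender matrix. In homeostatic replicate 3 and 3-day replicate 1 the CellBender matrix held more tdTomato than the main one, 7.66 against 0.424 and 11.7 against 0.386 per 10000 UMIs of fibroblast-like cells.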
